A study of Mus musculus with 2 samples.

How the data were processed

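Long-term hematopoietic stem cells were captured singly on a Fluidigm C1 microfluidic chip, their full-length cDNA was made with SMART-Seq v4 chemistry, and it was sequenced, per the labels' protocols. The deposited values are expected counts, estimated counts of reads per gene and cell, per the labels and the file headers. Reads were checked with FastQC 0.11.5 and MultiQC 0.8, aligned with STAR 2.5.2b to GRCm38 (mm10) and quantified with RSEM 1.3.0, and later steps used Seurat 2.3.4 under R 3.5.1, per the submitters' processing notes. RSEM divides reads that match several genes between them, so levels of genes with near-identical copies, such as ribosomal proteins with their pseudogenes and the Ifitm family, are less certain than those of single-copy genes. There are no molecular identifiers, and counts include PCR copies.

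The 2 tables held 23514 features each, 161 and 119 columns of cells, and at least 99.5% values that are exactly whole, with no tolerance. Expected counts were rounded to whole numbers. Of the features, 92 were spike-in sequences, which were left out of library totals, and 10 carried UCSC transcript names that the files do not pair with genes, which stayed in the totals. Of the remaining symbols and those 10 names, 23422 in all, 21780 were found in the GENCODE M21 annotation of GRCm38, from which chromosomes, coordinates and transcript lengths were taken. List members missing under their current symbol were looked up by older symbols in the RefSeq gene table of assembly GRCm38.p6. A cell was kept with at least 1000 genes and at least 100000 reads, which left 109 Pten+/+ and 89 PtenS398A/S398A cells. The planned limit on mitochondrial reads could not be applied, since no feature is named as mitochondrial. The study states 116 and 90 cells after its own quality control, by a filter that the labels do not give. Doublets were not called: no kept cell carried both Xist and Y-linked transcripts at 10 CPM, but the sets were of 1 sex each, so this says little about doublets. Chambers whose code starts with 2, which may mean 2 imaged cells, were kept, and the meaning of the codes is not given in the labels. A cell was classed male or female by Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty summed) or Xist at 10 CPM or more.

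For each genotype the counts of kept cells were summed and scaled by the summed total to CPM, the usual unit of library share, with an exact Poisson interval at 95%. The log2 ratio of PtenS398A/S398A over Pten+/+ was taken on CPM plus a pseudocount of 1, which understates differences of genes with low levels. Shares are of cells with at least 1 read, with exact Clopper-Pearson intervals. A gene was measured at 5 CPM and in 10% of cells of at least 1 genotype. Ratios were not centred. The median of all measured genes was -0.11 on the log2 scale, where another scaling gave -0.01 (TMM, edgeR). With this negative median, most measured genes counted as lower. The half-width of the Poisson interval was 21.6% of the level for Foxo3, the widest among the targets, the genes chosen by size and those fixed by name.

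There were 29 gene lists and 9 lists of markers of other cell types, fixed before the data were examined. A list's median log2 ratio over measured members was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and it is said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries. Lists with fewer than 5 measured members got no percentile. Genes named in the text follow a rule fixed beforehand. It takes Pten and Atm, then 14 genes higher and 14 lower with the largest value of the smaller of 2 log2 ratios (pooled CPM and mean CPM over cells), without Xist, Tsix, Y-linked, predicted and pseudogene names. These genes needed 20 CPM and reads in 20% of cells in 1 genotype, agreement in sign of both ratios, of the share of cells and of the ratios in male-classed and female-classed cells, and no cell with over 25% of the summed reads in the higher genotype. The rule passed 315 higher and 1307 lower genes before the limit of 14. These counts are no measure of gene-specific change. PtenS398A/S398A cells had fewer genes detected, and asking the share of cells to move with the ratio then favours lower genes. The rule adds up to 4 members of each list with the largest size of that smaller value, and 18 genes of stem cell identity and cycling whatever their value. The list members were picked for size among measured genes whose 2 ratios agree in sign, without the other limits. Their ratios are inflated by chance, and some may rest on few cells.

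The level, ratio and list steps were tested on simulated cells with the real library sizes, detection rates and mean levels of 13650 genes and 200 changed genes. The median recovered log2 ratio was 2.00 ± 0.58 (SD over 100 genes) for 4-fold changes and 0.99 ± 0.67 for 2-fold changes, with 100 and 90 of 100 in the right direction. A simulated list of 30 genes raised 1.5-fold stood at percentile 100, and 10 of 200 unchanged lists stood apart. The simulated genes vary independently, unlike real ones, so real lists stand apart by chance more often than this. Each simulated gene also had 1 detection rate in all cells. The gap in genes per cell between genotypes and the differences between sets were therefore not simulated.

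Alternatives were the mean over cells of each cell's CPM, TMM (edgeR) and DESeq2 size factors as scalings, pseudocounts of 0.1 and 5 CPM, other cell filters, removal of the 5 deepest cells, cells of 1 sex class, thinning to 100000 reads, and other filters and averages for lists. Alternatives added after the data were seen leave out or isolate column sets, weigh them equally, keep cells with few G2/M genes or chambers coded 1G, pair cells on genes per cell within 150 genes, or match random lists on transcript length. Another takes the 10 features with UCSC names out of the totals. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.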

Results

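Long-term hematopoietic stem cells were isolated by flow cytometry from mice of 2 genotypes, with a gate that excludes CD48 and requires Sca1, cKit and CD150, and their transcriptomes were sequenced cell by cell. Pten encodes a phosphatase that opposes phosphoinositide 3-kinase signalling, and in PtenS398A/S398A mice a serine near the carboxyl end of the protein is replaced by alanine (S398A). The study title places PTEN beside ATM, the kinase that responds to DNA breaks, in the control of stem cell fitness and dormancy. Each genotype was a pool of 3 male and 3 female mice and 1 deposited sample, so there are no replicates, and cells of a pool are not replicates of a genotype. All comparisons below therefore describe 2 pools of cells and carry no test. The deposited columns numbered 161 for Pten+/+ and 119 for PtenS398A/S398A, 280 in all as the study states. A minimum of 1000 genes and 100000 reads left 109 and 89 cells, where the study retained 116 and 90. The kept cells held 80581662 reads in Pten+/+ and 78870334 in PtenS398A/S398A, with medians per cell of 618519 and 806202. At this depth 8462 genes were measured.

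Column names carried a set number, 1 or 2, that followed sex in both genotypes. In Pten+/+, 28 of 35 cells of set 1 had Y-linked transcripts and none had Xist, while 53 of 74 cells of set 2 had Xist and none had Y-linked transcripts. In PtenS398A/S398A the same split held, with 31 of 44 cells of set 1 Y-positive and 35 of 45 cells of set 2 Xist-positive. The sets are called male and female below. They came from different animals and separate columns, so sex, animals and set cannot be told apart, and ratios within a set, given beside pooled ones for part of the genes and lists, are a split of the cells. Pooled ratios compare unequal shares of the sexes, with 74 of 109 Pten+/+ cells and 45 of 89 PtenS398A/S398A cells in the female set. So do comparisons that leave 1 set out. Over all measured genes the median log2 ratio was -0.02 within the male sets and -0.19 within the female sets. Counts of lower members and directions within a set are to be read against these negative medians. The 2 sets of one genotype differed across genes about as much as the genotypes did. With 35 cells drawn from each set, the SD of log2 ratios over genes was 1.32 between the Pten+/+ sets and 1.51 between the PtenS398A/S398A sets, against 1.38 between genotypes in male cells and 1.43 in female cells.

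Pten was transcribed at similar levels in both genotypes. Its pooled level was 205 CPM (95% Poisson interval 201 to 208) in Pten+/+ and 175 CPM (172 to 178) in PtenS398A/S398A, a log2 ratio of -0.23. Reads of Pten were found in 80.7% of Pten+/+ cells (exact binomial interval 72.1 to 87.7) and 74.2% of PtenS398A/S398A cells (63.8 to 82.9). The ratio was -0.15 in male and -0.28 in female cells. These intervals, like all others here, cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Pten (ENSMUSG00000013663.7) lies on chromosome 19 from 32757497 to 32826160 in GRCm38, and the codon of S398A occupies positions 32820008 to 32820010 in exon 9, the last of 9 coding exons. A gene count cannot show a codon change, so Pten reads do not check the genotype labels. Atm (ENSMUSG00000034218.16, chromosome 9 from 53439149 to 53536740) stood at 48.8 CPM (47.3 to 50.4) in Pten+/+ and 66.4 CPM (64.6 to 68.2) in PtenS398A/S398A. Its reads were in 33.9% and 41.6% of cells. The direction for Atm was opposite in the sets, with a log2 ratio of -0.40 in male cells and 1.46 in female cells.

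The first comparison asks whether stem cell and dormancy programs differed with the genotype. Genes of dormant stem cells were on balance lower in PtenS398A/S398A, with 15 of 22 measured members lower and 7 higher. Their median log2 ratio of -0.42 lay at percentile 0.09 of 10000 random lists of matched expression, in a background where the median of all measured genes was -0.11. Robo4, a receptor involved in niche retention, was at 21.9 CPM in Pten+/+ and 2.10 CPM in PtenS398A/S398A, and Art4 at 102 and 37.8 CPM. The cyclin-dependent kinase inhibitor Cdkn1c stood at 45.4 and 30.3 CPM, with reads in 30.3% and 18.0% of cells. Ifitm1 went the other way, at 1640 and 2630 CPM. In male cells alone the list median was -0.30 (percentile 0.73) and in female cells -0.23 (percentile 17.0). The list no longer stood apart in male-classed cells (-0.15, percentile 6.68), in female-classed cells (-0.05, percentile 49.0), or without the Pten+/+ male set (-0.05, percentile 27.3) or the PtenS398A/S398A male set (-0.41, percentile 5.21). The same held without cells bearing 3 markers of another cell type (-0.20, percentile 4.84) and without the 5 deepest cells of each genotype (-0.23, percentile 3.68). Whether the sets differ was not tested.

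Genes of stem cell identity leaned the same way without standing apart. Of 33 members 23 were lower, 9 of them beyond 1.5-fold, and the median of -0.22 was at percentile 6.69, with -0.36 (percentile 0.48) in male and -0.19 (percentile 35.2) in female cells, and -0.03 (percentile 45.6) without the Pten+/+ male set. The transcription factor Erg was at 23.6 CPM in Pten+/+ and 1.67 CPM in PtenS398A/S398A, Fgd5 at 32.3 and 6.72 CPM, and Hoxb5 at 25.8 and 8.81 CPM, and all 3 were lower in both sets. Procr, which encodes the stem cell surface receptor EPCR, was at 186 CPM (183 to 189) and 95.4 CPM (93.3 to 97.6), with log2 ratios of -1.38 in male and -0.43 in female cells. Hlf differed less, at 274 and 209 CPM, and Mecom was at 87.2 and 85.1 CPM. Ptpn21 was higher, at 1.46 and 7.20 CPM. Of the genes behind the sort gate, Kit stood at 313 and 253 CPM, Slamf1 at 127 and 93.2 CPM and Ly6a at 454 and 631 CPM, with opposite directions in male and female cells for Slamf1 (0.09 and -1.37) and Ly6a (-0.47 and 1.34). Vwf was at 71.5 and 63.4 CPM and Cd34 at 242 and 144 CPM. Reads of Cd48, excluded by the gate, were in 4.59% and 3.37% of cells, and those of Flt3 in 5.50% and 6.74%. Quiescence regulators were split, with 13 lower and 10 higher of 23 and a median of -0.05 at percentile 72.0. Among them Nr4a2 was lower in both sets (pooled log2 ratio -1.63). Tgfbr1 had a pooled log2 ratio of 0.84, with 1.16 in male and -0.30 in female cells, where the median of all measured genes was -0.19. Foxo3 was near the floor in both genotypes, with reads in 2.75% and 3.37% of cells.

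Cell cycle genes differed between the sets of one genotype as well as between genotypes. Female over male, the G2/M median was 3.77 in Pten+/+ and 0.96 in PtenS398A/S398A. Over all cells the G2/M list had a median of -0.26 (percentile 5.60), with 31 of 48 members lower, and the S phase list a median of -0.05 (percentile 66.0), with 20 of 38 lower. With the sets of each genotype weighed equally, these medians were -0.13 (percentile 37.9) and 0.02 (percentile 83.2). Within male cells the G2/M median was 1.99 (percentile 100), and within female cells -0.56 (percentile 1.03). The S phase median was 0.74 (percentile 100) in male and -0.33 (percentile 19.8) in female cells. Mki67, a marker of cycling cells, stood at 3.63 CPM in Pten+/+ male, 204 CPM in Pten+/+ female, 45.8 CPM in PtenS398A/S398A male and 120 CPM in PtenS398A/S398A female cells. Top2a had pooled levels of 116 and 84.0 CPM, with log2 ratios of 0.99 in male and -0.65 in female cells. Counting cells with at least 15 G2/M genes after thinning to 100000 reads, a limit chosen after the distribution was seen, there were 0 of 35 in the Pten+/+ male set, with an exact binomial interval up to 10.0%. The other sets had 29 of 74 in Pten+/+ female, 8 of 44 in PtenS398A/S398A male and 13 of 45 in PtenS398A/S398A female cells. The shares over both sets were 26.6% (exact binomial interval 18.6 to 35.9) and 23.6% (15.2 to 33.8), and 8 and 4 cells had 12 to 17 of these genes. These shares weigh the sets unequally, since 74 of 109 Pten+/+ cells and 45 of 89 PtenS398A/S398A cells were from the female set. Without thinning the shares over both sets were 28.4% and 23.6%. With a limit of 10 genes after thinning they were 44.0% and 27.0%. At that limit the shares were 22.9% and 22.7% in male cells, and 54.1% and 31.1% in female cells. At limits of 20 and 25 genes the male shares were 0% in Pten+/+ against 15.9% and 13.6% in PtenS398A/S398A.

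Among G1 regulators, 10 of 15 measured members were lower (median -0.27, percentile 10.7). Ccnd1, which encodes cyclin D1, was higher in PtenS398A/S398A in both sets, at 22.3 CPM (21.3 to 23.4) and 56.4 CPM (54.7 to 58.0). Cdk2 was lower, at 89.0 and 30.1 CPM. Cdk6 had few reads, at 5.78 and 2.62 CPM, and opposite directions in male (0.95) and female (-2.24) cells. Myc was at 255 and 222 CPM, with opposite directions in male (0.31) and female (-1.42) cells.

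**Figure D1:**
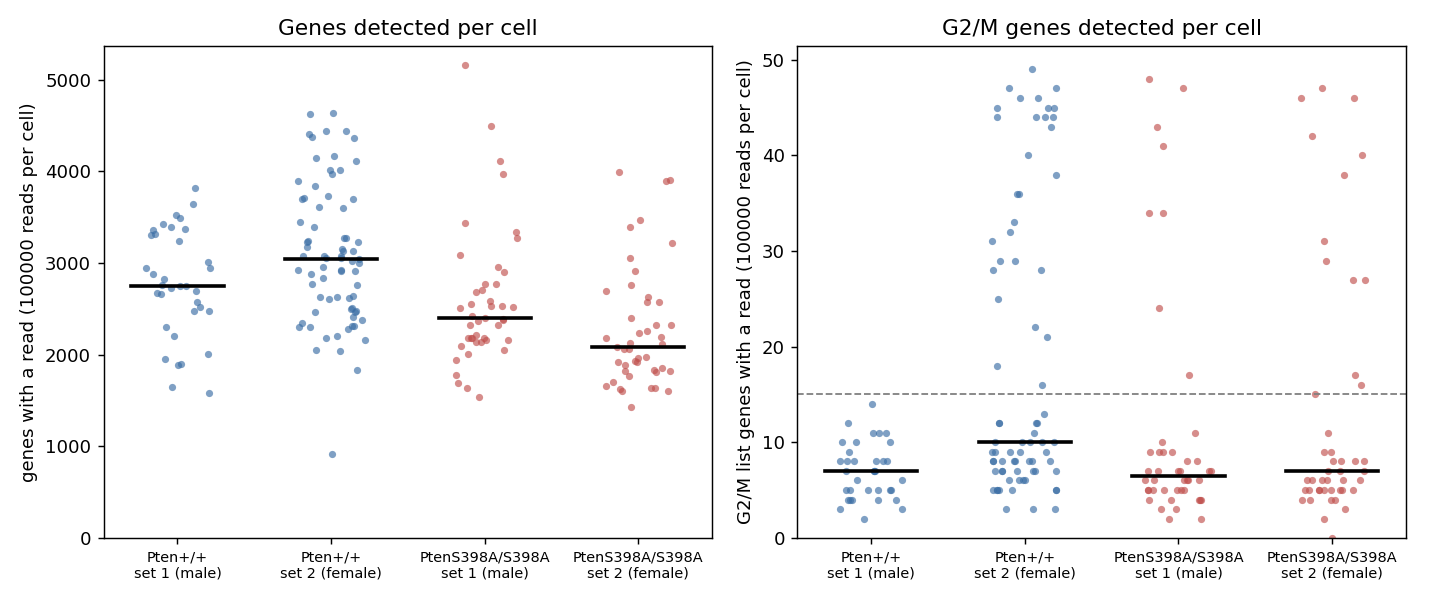
Each point is a kept cell, thinned to 100000 reads, and black bars are medians. The left panel plots genes detected per cell, with medians of 2753, 3047, 2396 and 2079 from left to right, and the right panel plots G2/M list genes detected per cell, with a dashed line at 15 genes above which the Pten+/+ male set has no cell.

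PTEN opposes AKT, a kinase that excludes FOXO factors from the nucleus, so FOXO targets and lists of growth and metabolism were compared next. FOXO targets were lower in PtenS398A/S398A, with 19 of 24 measured members lower, 11 of them beyond 1.5-fold, and 15 lower in both sets. The median of -0.40 lay at percentile 0.62, with -0.39 (percentile 0.94) in male and -1.02 (percentile below every random list) in female cells. Pink1, a kinase of mitochondrial quality control, was at 56.0 CPM in Pten+/+ and 12.3 CPM in PtenS398A/S398A, with reads in 46.8% and 22.5% of cells. The transcriptional repressor Hbp1 was at 380 and 160 CPM, the sphingosine receptor gene S1pr1 at 124 and 54.9 CPM, and the pocket protein gene Rbl2 at 86.4 and 42.4 CPM. Among the 5 higher members the largest ratio was that of Foxo1, at 22.2 and 48.9 CPM. Within each genotype the same list was also lower in female than in male cells, by a median of -0.57 in Pten+/+ and -1.47 in PtenS398A/S398A. Immediate early and handling stress genes went the same way in these comparisons, with a genotype median of -0.70 (percentile 0.03) in female cells and female over male medians of -0.83 and -1.51. In male cells their genotype median was -0.08 (percentile 13.4). Without the Pten+/+ male set the genotype median was 0.01 for FOXO targets and 0.40 for immediate early genes, and without the PtenS398A/S398A male set -1.37 and -1.35. Without the PtenS398A/S398A female set these medians were -0.17 and 0.36. Each of these settings compares 1 set of a genotype with both sets of the other, while both lists were lower in female than in male cells. Components of the PI3K-AKT-mTOR pathway had 16 of 24 members lower (median -0.41, percentile 5.22), with -0.79 (percentile 0.28) in male and -0.33 (percentile 32.5) in female cells, and 0.04 (percentile 76.1) without the Pten+/+ male set. Akt2 stood at 49.0 and 11.5 CPM, Deptor at 24.9 and 4.73 CPM, and Akt1s1 at 8.75 and 1.64 CPM. Targets of mTORC1 and SREBP had 16 of 26 members higher, with a median of 0.19 on the upper boundary for standing apart. Their median was 0.41 (percentile 97.1) in male cells. In female cells it was -0.25 (percentile 45.6), near the female median of all measured genes, -0.19. Without cells bearing 3 markers of another cell type the median was -0.02 (percentile 70.6). The cystine transporter gene Slc7a11 was at 1.19 and 12.2 CPM, whereas Slc7a5 was at 16.2 and 1.53 CPM.

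Transcripts for oxidative phosphorylation and cytosolic ribosomal proteins were higher in PtenS398A/S398A. Of 53 oxidative phosphorylation genes 43 were higher, 41 of them in both sets, and the median of 0.39 exceeded all random lists, as it did in female cells (0.45), with percentile 99.9 in male cells (0.33). Without the PtenS398A/S398A female set the list no longer stood apart (0.15, percentile 95.9). That setting compares male cells with cells of both sets, and female over male the list was at 0.32 in Pten+/+ and 0.40 in PtenS398A/S398A. Atp5e was at 143 CPM (141 to 146) and 252 CPM (248 to 255), and Atp5k at 53.8 and 99.9 CPM. Members lower by the largest ratios were Ndufs1, at 165 and 79.8 CPM, and Sdha, at 347 and 182 CPM. Of 76 ribosomal protein genes 74 were higher, 15 of them beyond 1.5-fold, with a median of 0.42 at percentile 100. They took 6.43% of reads in Pten+/+ and 8.33% in PtenS398A/S398A. Rps28 was at 210 and 360 CPM and Rps25 at 1178 and 1955 CPM. The ribosomal protein median was 0.18 (percentile 78.6) in male and 0.66 (percentile 100) in female cells. It was 0.18 (percentile 99.4) without the PtenS398A/S398A female set and 0.68 (percentile 100) without the male set of that genotype. Ribosome biogenesis and Myc targets had 20 of 33 members higher (median 0.19, percentile 97.6), but the list stood apart in neither set alone, at 0.22 (percentile 90.8) in male and 0.02 (percentile 78.2) in female cells. It was at 0.12 (percentile 93.1) with cells weighing the same, 0.05 (percentile 76.5) without cells bearing 3 markers of another type and -0.03 without the Pten+/+ male set. Its members included Hspe1 at 159 and 349 CPM, and Nop2, lower at 87.8 and 21.3 CPM. Glycolysis genes were lower in 19 of 23 cases (median -0.28, percentile 2.16), with -0.37 (percentile 0.31) in male and -0.28 (percentile 13.2) in female cells. This list no longer stood apart with cells weighing the same (percentile 8.85), after thinning (percentile 8.36), in cells paired on genes per cell (percentile 15.8), or without the Pten+/+ male set (-0.10, percentile 18.1). Pfkp was at 145 and 41.1 CPM, while Hk2 was higher at 25.3 and 65.3 CPM. The 13 mitochondrially encoded genes could not be measured, because the features carry no symbol for them.

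DNA damage and p53 target genes did not stand apart. Of 34 measured DNA damage response genes 22 were lower (median -0.21, percentile 28.9), with 0.03 (percentile 63.7) in male and -0.39 (percentile 25.3) in female cells. The histone gene H2afx was at 102 and 47.9 CPM, with log2 ratios of 0.09 in male and -1.97 in female cells, and the glycosylase gene Ogg1 at 26.2 and 10.1 CPM. Of 20 p53 targets 15 were lower (median -0.37, percentile 17.3), with Mdm2 at 93.7 and 36.1 CPM and Cdkn1a at 23.9 and 20.5 CPM, the latter with log2 ratios of 0.07 in male and -1.04 in female cells. Antioxidant genes had 21 of 34 members higher (median 0.15, percentile 91.2), and apoptosis regulators 9 of 15 lower (median -0.32, percentile 16.5), with opposite directions in male (-0.51) and female (0.32) cells. The apoptosis inhibitor gene Birc3 was at 60.5 and 2.78 CPM, with reads in 14.7% and 5.62% of cells. Interferon response genes were lower in 21 of 29 cases, with a median of -0.37 at percentile 0.92. In male cells this list stood at -0.53 (percentile 0.04) and in female cells at -0.26 (percentile 25.8). It was at -0.06 (percentile 67.2) in female-classed cells and -0.07 (percentile 36.4) without the Pten+/+ male set, and it no longer stood apart with cells weighing the same (-0.27, percentile 4.20) or without the 5 deepest cells (-0.27, percentile 7.74). Igtp was at 337 and 134 CPM, Gbp3 at 49.8 and 8.13 CPM, and Irf7 at 35.2 and 9.19 CPM, while Rsad2 was higher at 18.4 and 43.5 CPM. Autophagy genes were lower in 21 of 29 cases (median -0.35, percentile 2.63), including Wipi2 at 46.8 and 8.41 CPM. The autophagy median was -0.41 (percentile 1.29) in male cells and -0.49 (percentile 6.68) in female cells. With cells weighing the same it was -0.17 (percentile 24.5).

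The genes with the largest differences by the fixed rule were 14 higher and 14 lower in PtenS398A/S398A. Because they were picked for size, their ratios are inflated by chance, and all 28 also lay on one side in both PtenS398A/S398A sets against both Pten+/+ sets, which the rule in part required. The higher genes were Zfp26, Dnajc18, Ppm1h, Ankrd27, Dcaf17, Rlim, Lrif1, Gucy1a3, Trim24, Tor1b, Zfp91, Emd, Tmem97 and Kbtbd4, with log2 ratios from 1.35 to 2.71. Zfp26, a zinc finger gene on chromosome 9 (20428449 to 20460162), was at 8.85 CPM (8.21 to 9.52) and 63.5 CPM (61.8 to 65.3). The cochaperone gene Dnajc18 was at 6.59 and 35.6 CPM, and the X-linked ubiquitin ligase gene Rlim at 40.2 and 119 CPM, with reads in 39.4% and 49.4% of cells. The lower genes were Klhl4, Mylk, Slc25a46, Trappc12, Apeh, Msantd4, Ptger4, Tox, Arhgap25, Ikbkg, Cdkn2aip, Mgat4a, Tor4a and Cul4a, with log2 ratios from -4.21 to -2.27. Klhl4 on chromosome X (114474333 to 114560829) was at 101 CPM (98.6 to 103) and 4.49 CPM (4.03 to 4.98), with reads in 25.7% and 8.99% of cells. The myosin light chain kinase gene Mylk was at 42.4 and 3.49 CPM. The prostaglandin E2 receptor gene Ptger4, a member of the niche adhesion and homing list, was at 71.2 and 9.50 CPM. The HMG-box factor gene Tox was at 65.0 and 5.92 CPM, with reads in 37.6% and 15.7% of cells. Each of the 28 was read in under 50% of cells of either genotype, and a single cell held up to 21.9% of the summed reads of a higher gene in PtenS398A/S398A and up to 23.7% of those of a lower gene in Pten+/+.

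**Figure D2:**
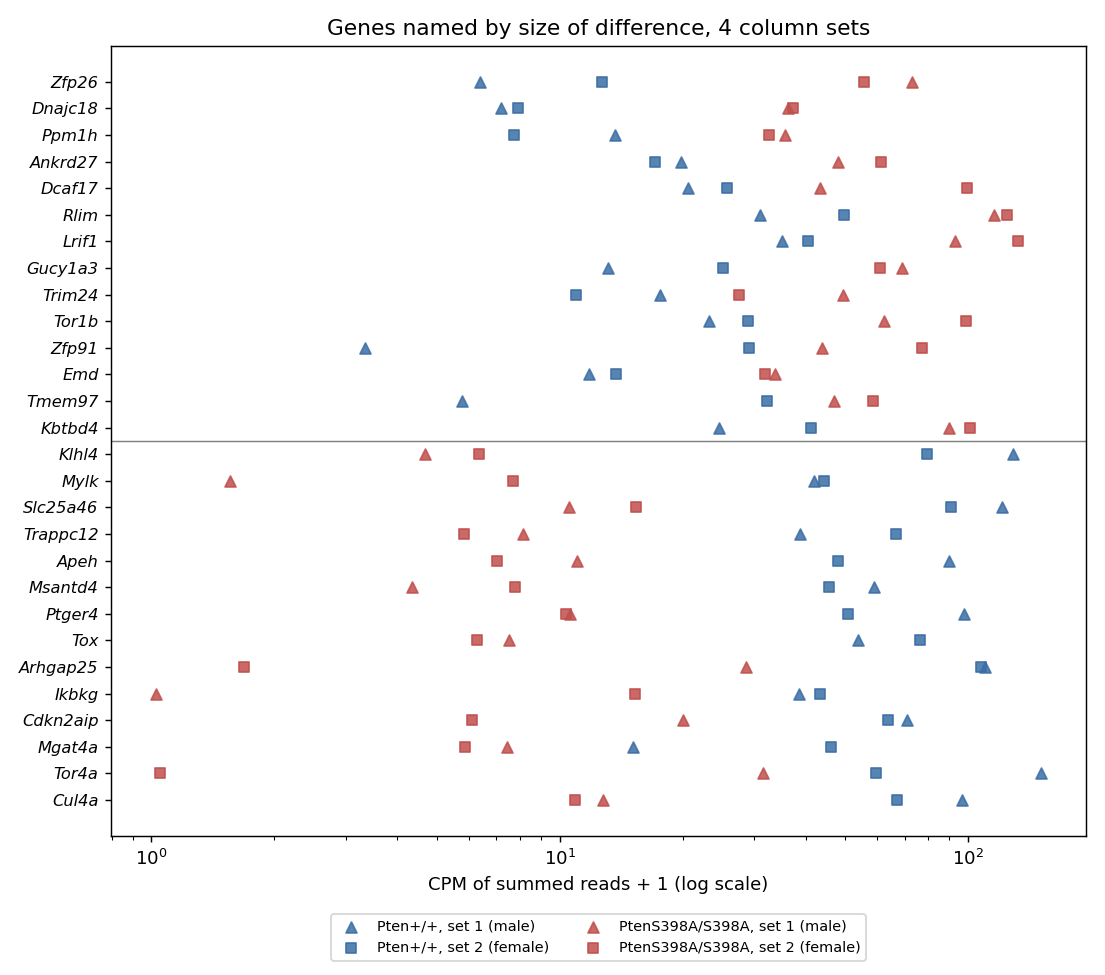
Levels of the 14 higher (top) and 14 lower (bottom) genes in the 4 column sets, as CPM of summed reads plus 1 on a log axis; colours mark genotype and symbols mark the set. The red symbols lie to the right of the blue ones for every gene above the line and to the left for every gene below it.

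Genes detected per cell were fewer in PtenS398A/S398A although its cells had more reads. Medians were 3203 genes (range 1056 to 5019) in Pten+/+ and 2494 (1714 to 5710) in PtenS398A/S398A. After each kept cell was thinned to 100000 reads, which left out no cell, they were 2940 and 2235. The order held within male cells (2753 and 2396) and within female cells (3047 and 2079), differences of -357 and -968 genes. The sets of one genotype differed by 294 genes in Pten+/+ and -317 in PtenS398A/S398A, female minus male. Fewer genes per cell in PtenS398A/S398A also lowers, on average, the shares of cells with a read given above for single genes. Scores per cell, the mean log2(CPM + 1) over list members, were lower in PtenS398A/S398A for 27 of 28 lists, 20 of them in both sets, and higher for ribosomal proteins, at 9.07 ± 0.41 (SD over 109 cells) and 9.45 ± 0.40 (SD over 89 cells). For oxidative phosphorylation the score was 6.76 ± 1.02 and 6.59 ± 1.04, lower over all cells although the pooled reads were higher. Within the sets this score was higher in male PtenS398A/S398A cells (6.44 and 6.57) and lower in female ones (6.91 and 6.60). For FOXO targets it was 3.32 ± 0.96 and 2.49 ± 0.95.

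**Figure D3:**
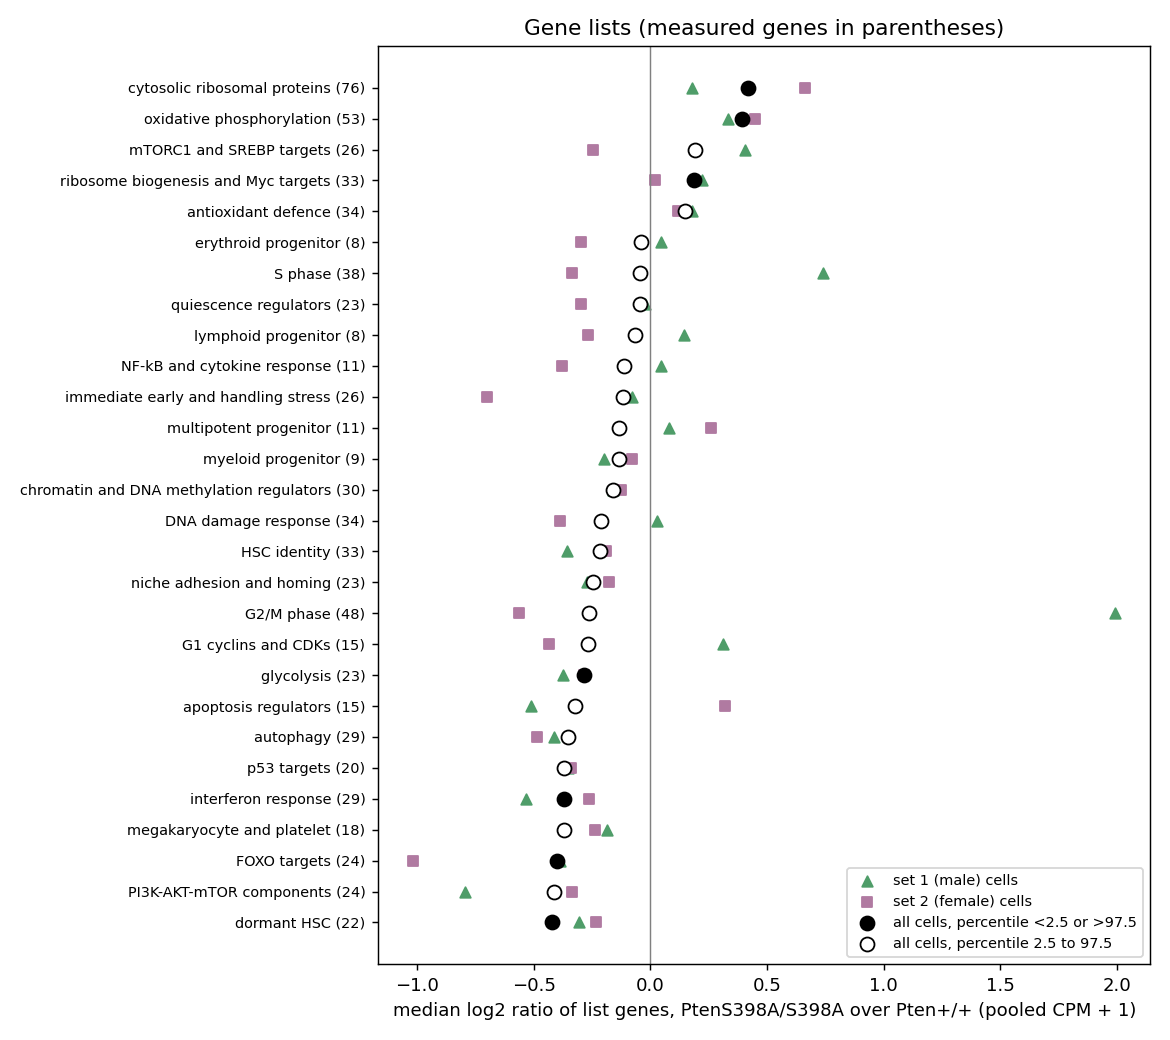
Median log2 ratio of the measured members of each gene list for all kept cells (circles), male sets (triangles) and female sets (squares), with the number of measured genes in parentheses. Filled circles are the lists that stand apart from random lists, from -0.42 for dormant stem cells to 0.42 for ribosomal proteins, and the G2/M triangle at 1.99 lies farthest from its circle.

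Of the 28 lists, 7 stood apart between genotypes, and at least as many did between the sets of one genotype. Between female and male cells 11 of 28 lists stood apart in Pten+/+ and 8 of 28 in PtenS398A/S398A. The comparison of genotypes gave 10 lists in male cells and 5 in female cells. Cells with 3 or more markers of another cell type at 50 CPM numbered 20 of 109 (18.3%) in Pten+/+ and 8 of 89 (8.99%) in PtenS398A/S398A. No cell had them for B cells, T or NK cells, neutrophils, stromal cells, or mast cells and basophils. Such cells numbered 3 and 2 for erythroid cells, 5 and 0 for endothelial cells, 2 and 0 for monocytes and macrophages, and 10 and 6 for megakaryocytes, in Pten+/+ and PtenS398A/S398A, and stem cells themselves share part of the megakaryocyte and endothelial markers.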

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

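The patterns weighed here were seen before their tests were chosen. The tests on differences between column sets and on overlapping intervals were also chosen after their values were known. The G2/M list drew attention because its median log2 ratio was 1.99 in male and -0.56 in female cells, opposite directions in the sexes, and this difference was not tested. Atm also went in opposite directions, at -0.40 in male and 1.46 in female cells, a difference that was not tested. Signals also appeared in features that no comparison examines, of which those with UCSC names stayed in the library totals. Spike-in sequences took a median of 1.29% of reads in the male set of PtenS398A/S398A and at most 0.00637% in any Pten+/+ cell and 0.00631% in any female PtenS398A/S398A cell, so they mark 1 column set rather than a genotype. That set, which was thus handled differently, enters every genotype ratio in male cells. Features with UCSC transcript names took a median of 4.62% of reads in Pten+/+ and 5.67% in PtenS398A/S398A.

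Ribosomal protein and oxidative phosphorylation genes were higher in PtenS398A/S398A. Among random lists matched on expression and on the longest annotated transcript of each gene, the percentiles stayed at 100 and 99.99. This argues against transcript length as the whole cause. It does not exclude it, since the length groups were coarse and the longest transcript need not be the one expressed. Fewer genes per cell stays undecided. In cells paired on that number the percentiles were 99.99 and 100, but pairing also changed the mix of cells. The paired cells were 22 male and 40 female in Pten+/+ against 35 and 27 in PtenS398A/S398A, and their G2/M median was 1.23. Differences between column sets remain possible. Female over male, the ribosomal protein median was -0.01 in Pten+/+ and 0.51 in PtenS398A/S398A, and the oxidative phosphorylation median 0.32 and 0.40. The larger values, 0.51 and 0.40, were no less than the smaller genotype ratios within a sex, 0.18 and 0.33. This decides nothing, since the larger value was set against the smaller ratio and a difference shared by both genotypes cancels within a sex. Without the PtenS398A/S398A female set oxidative phosphorylation was at 0.15 and no longer stood apart. That setting compares male cells with cells of both sets. The genotype could also account for the pattern. With 1 pool per genotype it cannot be separated from the animals or from capture and library steps, since the columns give no chip holding both genotypes.

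The G2/M list was higher in male and lower in female PtenS398A/S398A cells. Chambers whose code starts with 2, which may mean 2 cells, held 6% of the cells with at least 15 G2/M genes. So few such chambers were kept that a low share was fixed in advance. Other codes that may also mean more than 1 cell were not counted, so chambers with 2 cells stay undecided as a cause. Chance capture of few cycling cells stays undecided: the exact intervals of the genotypes overlap in 2 of 2 sexes, which is no test of equal shares, and the male PtenS398A/S398A share of 18.2% lies above the Pten+/+ interval. The intervals were 0% to 10.0% against 8.19% to 32.7% in male cells, and 28.0% to 51.2% against 16.4% to 44.3% in female cells. With a limit of 10 genes the male shares were 22.9% and 22.7%, so the male difference in shares depends on the limit. That limit cuts through the many male cells with 7 to 12 genes, 18 of 35 in Pten+/+ and 14 of 44 in PtenS398A/S398A. At limits of 20 and 25 genes the male shares were still apart, 0% in Pten+/+ against 15.9% and 13.6% in PtenS398A/S398A. An effect of genotype that depends on sex could give the same picture and was not tested.

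FOXO targets were lower in PtenS398A/S398A. Fewer genes per cell stays undecided: the list still stood apart in paired cells (percentile 1.59), but pairing also changed the mix of sets and cycling cells. Handling stress remains possible: the percentile without the 2 members shared with the immediate early list, 0.11, decides nothing because both lay above the list median, while that list was lower in female cells (-0.70) but little changed in male cells (-0.08), where FOXO targets were at -0.39. Differences between column sets remain possible. Female over male, the FOXO target median was -0.57 in Pten+/+ and -1.47 in PtenS398A/S398A, so up to 1.47 in size. The genotype ratios were -0.39 in male and -1.02 in female cells. Setting these values side by side decides nothing, since a difference shared by both genotypes cancels within a sex. Lower FOXO activity with the S398A change could account for the lower FOXO targets as well and was not tested.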

How the results depend on the processing

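Of the values of 28 lists under 28 alternatives, 683 stayed on their side of the limits, 46 became weaker, 44 stronger and 11 reversed, with direction taken relative to random lists. By the sign of the median alone, 86 differed from the reported value. Only the 7 lists that stood apart could become weaker, and a list inside the limits counts as unchanged wherever it moves within them. The 14 lists set as main results, among them all 7 that stood apart, held 320 unchanged, 46 weaker, 17 stronger and 9 reversed values. Changes of the remaining lists are given below only in part. All 28 genes chosen by size kept their direction under all 24 alternatives for genes. The rule that chose them fixed this in advance for the mean over cells and for each sex class. Pseudocounts cannot change a sign, other scalings shift these ratios little, and the column sets hold the cells of the sex classes. In size, 125 values of these genes, Pten and Atm moved by more than the spread between sets and 595 did not. In female-classed cells the smallest ratio in size was 0.26, against 1.35 over all cells. Alternatives that use single column sets, leave sets out, keep chambers coded 1G or cells with under 15 G2/M genes, pair cells on genes per cell, or match lists on length were added after the data were seen. So were those that weigh the sets equally or take the features with UCSC names out of the totals. For each change below the cause was not tested. Settings that leave a set out compare 1 set of a genotype with both sets of the other. In the male set alone the medians were -0.36 for HSC identity, 0.74 for S phase, 1.99 for G2/M, -0.79 for PI3K-AKT-mTOR components, 0.18 for ribosomal proteins and 0.22 for ribosome biogenesis. In male-classed cells they were -0.51 for HSC identity, -0.15 for dormant HSC, 1.16 for S phase, 2.27 for G2/M, -0.32 for FOXO targets, -0.23 for glycolysis, 0.12 for ribosomal proteins and 0.29 for ribosome biogenesis. In the female set alone they were -0.23 for dormant HSC, -0.56 for G2/M, -0.28 for glycolysis, 0.0221 for ribosome biogenesis and -0.26 for interferon response. In female-classed cells they were -0.051 for dormant HSC, -0.18 for glycolysis, -0.0876 for ribosome biogenesis and -0.0643 for interferon response. Without the Pten+/+ male set they were -0.0521 for dormant HSC, -0.46 for S phase, -0.94 for G2/M, 0.00884 for FOXO targets, 0.0419 for PI3K-AKT-mTOR components, -0.10 for glycolysis, -0.0334 for ribosome biogenesis, -0.0735 for interferon response and 0.40 for immediate early genes. Without the Pten+/+ female set they were -0.41 for HSC identity, 1.06 for S phase, 2.77 for G2/M, -0.70 for p53 targets and 0.30 for ribosome biogenesis. Without the PtenS398A/S398A male set they were -0.41 for dormant HSC, 0.15 for G2/M, -0.43 for glycolysis, 0.0694 for ribosome biogenesis and -0.37 for interferon response. Without the PtenS398A/S398A female set they were -0.67 for G2/M, -0.17 for FOXO targets, -0.20 for glycolysis, 0.15 for oxidative phosphorylation, 0.0497 for ribosome biogenesis and 0.36 for immediate early genes. With cells weighing the same, G2/M was at -0.40, glycolysis at -0.17, ribosome biogenesis at 0.12 and interferon response at -0.27. Cells with a sex class gave -0.41 for HSC identity and 0.22 for S phase, and the stricter cell filter 0.16 for S phase and -0.27 for glycolysis. Without the 5 deepest cells dormant HSC was at -0.23, ribosome biogenesis at 0.12 and interferon response at -0.27, and without cells bearing 3 markers of another type dormant HSC was at -0.20, glycolysis at -0.25 and ribosome biogenesis at 0.0472. After thinning G2/M was at -0.36, glycolysis at -0.19 and ribosome biogenesis at 0.11, and in 1G chambers glycolysis was at -0.26 and ribosome biogenesis at 0.19. Paired cells gave 0.50 for S phase, 1.23 for G2/M and -0.12 for glycolysis, and length matching left glycolysis at -0.28 inside the limits. Ribosome biogenesis was at 0.19 with a pseudocount of 0.1 CPM, 0.14 in cells with under 15 G2/M genes, 0.17 without the filter on low values and 0.0307 as a mean over members. TMM moved the median of all genes from -0.11 to -0.01, a shift of 0.10. No paired analysis was possible because each genotype has 1 sample and the labels carry no replicate numbers. Totals without mitochondrially encoded genes were not run, since no feature carries those symbols, and neither were chips or plates holding both genotypes, which the columns do not give. At this depth genes under about 5 CPM were not compared.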

Other observations

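Among lineage genes, megakaryocyte and platelet genes were lower in 15 of 18 cases (median -0.37, percentile 3.06; 0.08 in male-classed and -0.27 in female-classed cells; -0.17 and percentile 25.8 without cells bearing 3 markers of another cell type), with Plek at 124 CPM in Pten+/+ and 63.5 CPM in PtenS398A/S398A, Fli1 at 122 and 68.2 CPM, and Itga2b at 47.3 and 22.9 CPM. Erythroid progenitor genes were split, 4 lower and 4 higher (median -0.04, percentile 54.5), with Tfr2 at 97.3 and 37.0 CPM and Car2 at 2686 and 3655 CPM. The myeloid progenitor list had a median of -0.13 (percentile 34.4), with Csf3r at 38.6 and 60.0 CPM and opposite directions in male (-0.20) and female (1.10) cells. The lymphoid progenitor list had a median of -0.07 (percentile 52.6), and the multipotent progenitor list one of -0.13 (percentile 23.7).

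Niche adhesion and homing genes were lower in 15 of 23 cases (median -0.25, percentile 4.43; -0.06 without the Pten+/+ male set), among them Tek, at 37.9 and 20.3 CPM. Chromatin and DNA methylation regulators were lower in 17 of 30 cases (median -0.16, percentile 43.3). Dnmt3a was at 33.6 and 12.3 CPM and Sirt1 at 47.2 and 15.8 CPM, while Tet3 was at 19.2 and 36.4 CPM. The NF-kB and cytokine response list had a median of -0.11 (percentile 49.1). Immediate early and handling stress genes had a median of -0.12 (percentile 15), with -0.08 in male and -0.70 in female cells. They were lower in female than in male cells of the same genotype, by -0.83 in Pten+/+ and -1.51 in PtenS398A/S398A.

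Procr was read in 17.2% of cells with at least 15 G2/M genes and 68.9% of other cells in the Pten+/+ female set, in 25% and 55.6% in the PtenS398A/S398A male set, and in 15.4% and 56.2% in the female set. Hlf was read in 65.5% and 86.7%, 75.0% and 86.1%, and 61.5% and 78.1% of cells. Female over male, the S phase median was 1.37 in Pten+/+ and 0.50 in PtenS398A/S398A.

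A hypothesis was that sequence linked to the edited allele changes the level of genes near Pten on chromosome 19. The 35 measured genes within 5 Mb had a median log2 ratio of -0.08 at percentile 60.4, with 15 higher and 20 lower, which speaks against a shared shift of these genes.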
